A study of Homo sapiens with 16 samples.

How the data were processed

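Poly(A) RNA was sequenced from 16 libraries in 8 groups of 2, from the human cell lines U2OS (osteosarcoma) and HCT116 (colorectal carcinoma). Per the labels' protocols, U2OS cells received a pool of siRNAs against SAM68 or a non-targeting control pool, or a plasmid with the mouse SAM68 gene or the empty control plasmid. HCT116 cells, wild type or SAM68 knockout, received siRNAs against NORAD or the control pool. The labels give 50 nM siRNA, 100 ng plasmid per 20000 cells and harvest after 48 h. RNA was isolated with TRI reagent and made into libraries with a strand-specific mRNA kit, per the labels' protocols. Whether the 2 libraries of a group came from separate cultures is not stated in the labels, so p-values measure only the spread between these samples, which may be technical.

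Per the file headers, the deposited values are RSEM gene estimates over RefSeq transcripts, with 1 file per library and no pooling. The expected counts, which are estimated read counts and need not be whole, were used as deposited by the authors, without normalization, and rounded to whole numbers for the tests. The effective length in bases, another column deposited by the authors, served only as an offset in 1 alternative. STAR, RSEM and the genome build hg19 are named in the submitters' processing notes. Their versions, and whether counting used the strand, are not given in the sources used here. Antisense, overlapping and near-identical genes are therefore uncertain. The TPM and FPKM columns were not used here.

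The files hold 27434 rows with NCBI gene numbers or transcript names. A symbol was found by gene number for 25321 of them and by transcript for 53. A further 166 joined rows carried 1 symbol, 457 joined several copies of a gene, 1252 were rows of further genomic copies, and 185, with 0.05% of the counts, had no symbol. The gene annotation used here (GENCODE release 29, and the RefSeq table of assembly GRCh38.p14) belongs to another build than the files. It served for names, gene neighbours and 3′ UTR sequences, and no coordinates are printed.

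Library depth was the sum of expected counts, 11349545 to 27387412 per library. The replicates of each group differed by more than sampling noise, with a chi-square per gene of 7.85 to 60.1 over genes with a combined count of at least 20, and log CPM correlated across genes at 0.965 to 0.991. All 16 libraries were kept as separate samples.

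Each cell line was fitted apart with its 4 groups, which share the estimate of the spread, because 2 libraries per group give too few degrees of freedom alone. Counts were filtered with filterByExpr and scaled by TMM, and tested with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest; edgeR 4.0.16, limma 3.58.1, R 4.3.3). Calls had a Benjamini-Hochberg adjusted p below 0.05 across all tested genes, 15658 in U2OS and 13764 in HCT116. The biological coefficient of variation was 20% in U2OS and 11.3% in HCT116. Log2 fold changes are given with their standard error, and levels as CPM (counts scaled to a common library total) with mean ± SD with n = 2. Exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333. The 6 comparisons were SAM68 siRNA and SAM68 plasmid in U2OS, NORAD siRNA in wild-type and in knockout HCT116, the difference of these NORAD effects, and knockout against wild type under control siRNA.

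A total of 18 gene lists were fixed: reported Pumilio targets, reported SAM68 targets, STAR family and NORAD protein partners, mitosis, DNA replication and repair, p53 targets, interferon-stimulated genes, integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, NF-kB and inflammatory genes, immediate early genes, hypoxia and glycolysis, colon epithelial markers, mesenchymal and bone markers, blood, endothelial and liver markers, ribosomal proteins, and histones. Lists with at least 5 tested members were compared with all other genes by camera (limma) with a preset correlation of 0.01, adjusted over 102 list tests. Camera with an estimated correlation and fry were run beside it. A separate list held 1639 genes whose longest annotated 3′ UTR has at least 2 copies of TGTANATA, the Pumilio binding motif, among 18020 genes with a 3′ UTR. Its 6 camera tests against all other tested genes form their own family, as do those against each matched background. A scrambled motif, TATGNATA, gave a control list of 751 genes.

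The named genes were fixed by rule: KHDRBS1 (the gene of SAM68), NORAD and PUM2 in each comparison (1 further gene is not reported here); the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups; for the difference of effects 5 each; and, for each called list, the 3 members with the smallest p in its direction and a called member that moved most clearly the other way, of which there was none. Up to 5 called motif genes per direction were to be named in the NORAD comparisons, where none was called. Unnamed locus and antisense symbols were left out of this rule. The comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

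Alternatives were DESeq2 1.42.0, other size factors, no filter or a filter of 1 CPM in 2 libraries, a fold threshold of 1.2, an effective length offset, only the compared libraries, the replicate number as a block, and each library left out in turn. In the last, the lone library of a group is assumed to vary like the other groups. Chosen after seeing the data were leaving out copy rows, matching on 3′ UTR GC content, an offset for 3′ UTR GC content and length (a spline with 4 degrees of freedom), knockout against wild type under NORAD siRNA, and the lists without single libraries. The offset does not model the GC content of the rest of the transcript. Heptamers in 3′ UTRs of at least 50 bases, held by at least 50 genes, were ranked by mean log2 fold change. The fold changes were first corrected by splines for 3′ UTR length, 3′ UTR GC content and expression. The 40 permutations were made with the corrected values of knockout against wild type under control siRNA. Shared control libraries were simulated in 30 draws. Figures and sequence searches used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

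The test was checked on simulated counts with 200 changed genes, beside a raised p53 target list. The counts were drawn independently for each gene, without the GC trends between replicates of the real libraries. Planting 200 changed genes also eases the adjusted p threshold. In the real SAM68 siRNA fit, with 1 called gene, KHDRBS1 changed 3.82-fold and had an edgeR adjusted p of 0.185. For both reasons the recovery rates may be too high for the real data. For SAM68 siRNA in U2OS, over 15658 genes, it recovered 2% of changes of 1.5-fold, 24% of 2-fold, 90% of 4-fold and 94% of 8-fold, with 18 unchanged genes called. For NORAD siRNA in wild-type HCT116, over 13764 genes, it recovered 34%, 62%, 92% and 98% at these folds, with 13 unchanged genes called.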

Results

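RNA-seq was run on 2 human cell lines in which the RNA-binding protein SAM68 (gene KHDRBS1, NCBI gene 10657) or the long noncoding RNA NORAD (NCBI gene 647979) had been perturbed. The series asks whether SAM68 is needed for NORAD to regulate Pumilio proteins, which bind and repress mRNAs through a motif in their 3′ UTR. NORAD itself carries 15 copies of that motif in a transcript of 5339 bases. There were 8 groups of 2 libraries. Total expected counts in U2OS were 20546956 and 25764664 under control siRNA, 11349545 and 19367913 under SAM68 siRNA, 14097320 and 22392590 under control plasmid, and 14562864 and 23910417 under SAM68 plasmid. In wild-type HCT116 they were 21425126 and 16203278 under control siRNA and 25589861 and 19109624 under NORAD siRNA. In SAM68 knockout HCT116 they were 15808640 and 20223783 under control siRNA and 18930547 and 27387412 under NORAD siRNA.

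The targeted genes moved in the direction of their labels in every library. KHDRBS1 was at 244.7 and 248.7 CPM under control siRNA in U2OS and at 80.7 and 48.6 CPM under SAM68 siRNA. It was at 219.9 and 276.9 CPM with the control plasmid and at 530.6 and 593.3 CPM with the SAM68 plasmid, which carries the mouse gene, so these are the reads that aligned to the human one. In HCT116, KHDRBS1 was at 217.2 and 241.3 CPM in the wild-type and 31.6 and 38.5 CPM in the knockout libraries under control siRNA, and at 206.3 and 224.1 against 34.4 and 44.5 CPM under NORAD siRNA. NORAD was at 249.2 and 232 CPM under control siRNA and 50.2 and 47.4 CPM under NORAD siRNA in wild-type cells, and at 224.7 and 251.7 against 77.4 and 54.7 CPM in knockout cells. NORAD in U2OS, where it was not targeted, lay between 254.3 and 445.9 CPM.

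**Figure D1:**
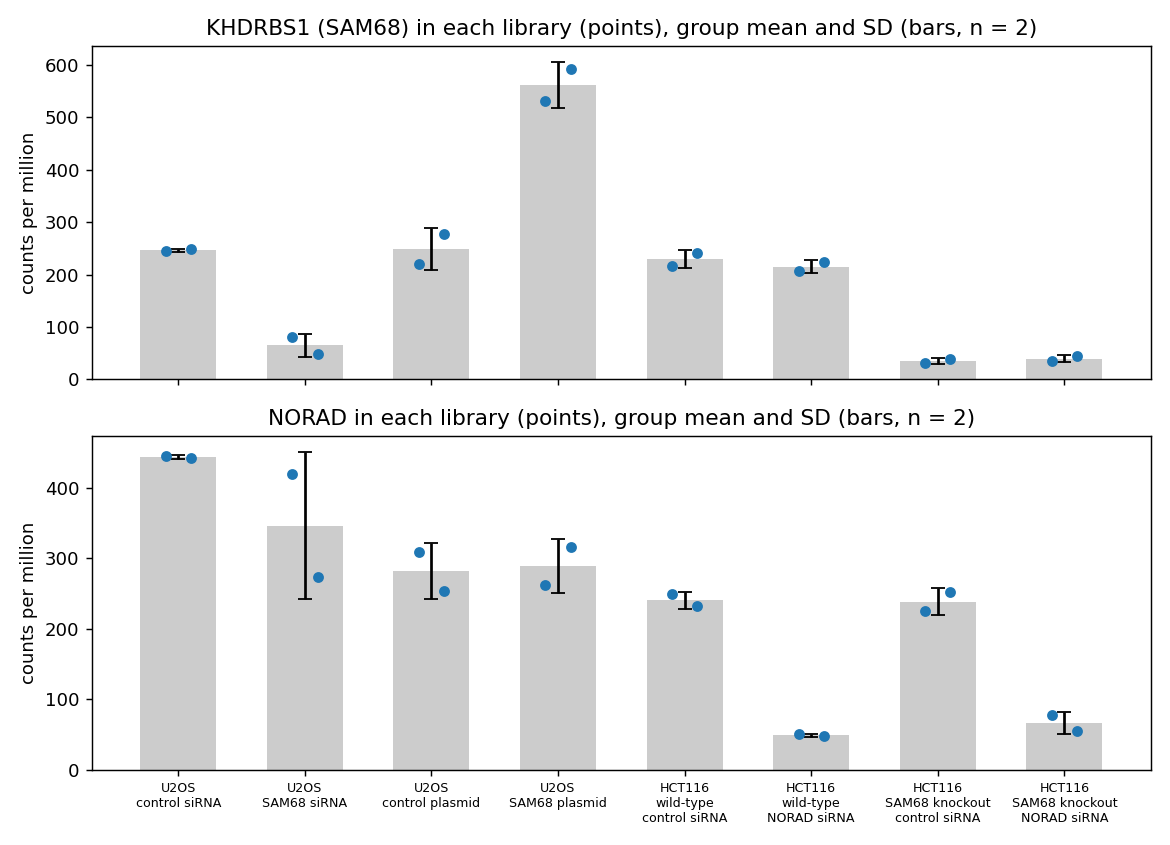
CPM of KHDRBS1 (top) and NORAD (bottom) in each of the 16 libraries (points), with the group mean (grey bars) and SD (n = 2). KHDRBS1 lies at 64.6 CPM under SAM68 siRNA against 247 in its control and at 35.1 CPM in knockout against 229 in wild-type HCT116; NORAD lies at 48.8 and 66.0 CPM under NORAD siRNA.

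SAM68 siRNA in U2OS left 26.2% of KHDRBS1 mRNA, 64.6 ± 22.7 CPM against 247 ± 2.80 (SD, n = 2). The log2 fold change was -1.94 ± 0.25 (SE), with an edgeR adjusted p of 0.185. DESeq2 gave an adjusted p of 1.26e-09, and edgeR without SAM68 siRNA replicate 1 gave 0.00817 at -2.26, in a range of 1.26e-09 to 0.741 over 6 alternatives. NORAD (log2 -0.36, 347 ± 104 against 444 ± 2.54 CPM) and PUM2 (-0.31) did not pass the test, each with an edgeR adjusted p of 1. Mitosis genes lay lower as a group, with 40 of 46 members negative and a median log2 of -0.182 (camera adjusted p = 8.88e-05; adjusted p = 0.786 with an estimated correlation). Their smallest p belonged to BUB1B (-0.47 ± 0.25) and BUB1 (-0.43 ± 0.24), kinases of the spindle checkpoint, and STAG1 (-0.49 ± 0.28), a cohesin subunit. Immediate early genes lay higher, 18 of 22 members with a median of 0.285 (camera adjusted p = 0.00013; adjusted p = 0.786 with an estimated correlation), among them the transcription factors FOSB (1.18 ± 0.56), FOSL1 (0.36 ± 0.20) and MYC (0.33 ± 0.17). No member of either list passed the edgeR test over all genes or adjusted over the list alone.

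Both list results depended on single U2OS libraries. Without SAM68 siRNA replicate 2 the mitosis median was -0.013 (camera adjusted p = 0.836), and the immediate early median turned to -0.104 (0.457). Without control siRNA replicate 1 these were -0.059 (0.0309) and 0.110 (0.321), without control siRNA replicate 2 -0.293 and 0.538, and without SAM68 siRNA replicate 1 -0.473 and 0.608. With an offset for 3′ UTR GC content and length, chosen after seeing the data, the mitosis median was -0.108 (camera adjusted p = 0.000244). Across all genes, edgeR called 1 of 15658, with 166 at an unadjusted p below 0.05 where 783 would be expected by chance, and DESeq2 called 7. Single libraries set that count of 166, which was 1899 without SAM68 siRNA replicate 1, 562 without SAM68 siRNA replicate 2 and 83 without control siRNA replicate 1. The called one was a row for a further genomic copy of ZBED1, at 8.85 ± 0.513 CPM against 0. Its 4 rows summed to 19.3 and 31.81 CPM under SAM68 siRNA against 22.49 and 28.02 under control, and single rows of such copies are uncertain. Over 6 alternatives the adjusted p of this row ranged from 7.58e-08 to 0.0927. The number of called genes was 0 without control siRNA replicate 2, 2 without SAM68 siRNA replicate 1 and 5 without SAM68 siRNA replicate 2. The groups did not overlap for 18.9% of genes, where chance gives 33.3%. Log2 fold changes rose with 3′ UTR GC content across genes (Spearman rho 0.394) and with that of the rest of the transcript (0.414). For 3′ UTR GC content, replicate 2 over replicate 1 gave 0.565 within the SAM68 siRNA group and 0.406 within its control. EdgeR with the offset called 1 gene, lower. The ZBED1 row has no annotated 3′ UTR and was not part of that fit.

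SAM68 plasmid in U2OS gave KHDRBS1 at 562 ± 44.3 CPM against 248 ± 40.3 (SD, n = 2), a log2 fold change of 1.18 ± 0.24. The edgeR adjusted p was 1 and the DESeq2 adjusted p 0.0162, in a range of 0.0162 to 1 over 6 alternatives. NORAD (0.04) and PUM2 (-0.10) had an edgeR adjusted p of 1. Ribosomal protein genes lay higher, with 76 of 77 members positive and a median log2 of 0.247 (camera adjusted p = 1.57e-13; adjusted p = 0.786 with an estimated correlation). RPS28 (0.51 ± 0.28), RPLP2 (0.49 ± 0.26) and RPL39 (0.42 ± 0.22) had the smallest p among them, and none passed the edgeR test over all genes or adjusted over the list alone. The direction rested on 1 library: without SAM68 plasmid replicate 1 the median was -0.134 (camera adjusted p = 1.02e-07, lower), and without SAM68 plasmid replicate 2 it was 0.539. The GC and length offset gave 0.159 (1.14e-09).

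EdgeR called 1 of 15658 genes with the plasmid, the same copy row of ZBED1 (9.21 ± 2.59 CPM against 0), while the 4 rows summed to 20.46 and 21.16 CPM against 21.28 and 23.49. The unadjusted p was below 0.05 for 86 genes, against 783 expected by chance, but for 1034 without SAM68 plasmid replicate 2, and DESeq2 called 4. The number of called genes was 0 without control plasmid replicate 1, 0 without SAM68 plasmid replicate 1 and 4 without control plasmid replicate 2. Without SAM68 plasmid replicate 2 the ZBED1 row had an adjusted p of 0.0673, in a range of 9.48e-07 to 0.126 over 6 alternatives, and the 1 called gene was another one, lower. The groups did not overlap for 18.0% of genes, against 33.3% by chance. Log2 fold changes rose with 3′ UTR GC content (rho 0.233) and with that of the rest of the transcript (0.24). For 3′ UTR GC content, replicate 2 over replicate 1 gave rho 0.499 within the control plasmid and -0.408 within the SAM68 plasmid group.

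NORAD siRNA in wild-type HCT116 left 20.3% of NORAD, 48.8 ± 1.99 CPM against 241 ± 12.1 (SD, n = 2). NORAD fell by 2.30 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00099), and it was the called gene, 1 of 13764. KHDRBS1 (-0.09) and PUM2 (-0.09) had an edgeR adjusted p of 0.999. Hypoxia and glycolysis genes lay higher, 25 of 27 members with a median log2 of 0.159 (camera adjusted p = 1.63e-05; adjusted p = 0.786 with an estimated correlation), including the peptide hormone gene ADM (0.40 ± 0.16), the glycolytic regulator PFKFB4 (0.52 ± 0.35) and the enolase ENO2 (0.34 ± 0.22). This list was called in each fit without 1 of the 4 libraries, with medians of 0.158 to 0.220. Ribosomal protein genes also lay higher, 72 of 75 with a median of 0.099 (camera adjusted p = 8.44e-05; adjusted p = 0.941 with an estimated correlation), led by RPL36 (0.27), RPL38 (0.24) and RPS21 (0.23). Integrated stress response genes lay lower, 17 of 21 with a median of -0.10 (camera adjusted p = 0.00445), among them the cystine transporter SLC7A11 (-0.34 ± 0.18), the asparagine synthetase ASNS (-0.23 ± 0.11) and PPP1R15A (-0.31 ± 0.20). Endoplasmic reticulum chaperones were lower in 12 of 16 members, with a median of -0.09 (camera adjusted p = 0.0226) and HYOU1 (-0.28 ± 0.11), HSPA5 (-0.28 ± 0.18) and DNAJC3 (-0.32 ± 0.17) at its head. These last 2 lists had an adjusted p = 0.786 with an estimated correlation, and no member of the 4 lists passed the edgeR test over all genes or adjusted over the list alone.

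Besides hypoxia, these wild-type lists each lost their call without single libraries. Without control siRNA replicate 2 the ribosomal median was 0.017 (camera adjusted p = 0.738) and the chaperone median -0.031 (0.465). Without control siRNA replicate 1 the stress response median was -0.014 (0.359), the ribosomal 0.196 and the chaperone -0.175. Without NORAD siRNA replicate 1 the ribosomal median was -0.001 (0.846) and the stress response -0.179. Without NORAD siRNA replicate 2 the stress response median was -0.04 (0.374), the chaperone -0.111 (0.185) and the ribosomal 0.196. The stress response median was -0.169 without control siRNA replicate 2. The ribosomal median was 0.064 (0.00387) with the GC and length offset. At an unadjusted p below 0.05 there were 181 genes, against 688 expected by chance, and DESeq2 called 5. This count was 917 without control siRNA replicate 1 and 105 without NORAD siRNA replicate 1. EdgeR called 2 genes without NORAD siRNA replicate 1. The groups did not overlap for 27% of genes, against 33.3% by chance. Log2 fold changes rose with 3′ UTR GC content (rho 0.377) and with that of the rest of the transcript (0.361). For 3′ UTR GC content, replicate 2 over replicate 1 gave rho -0.478 under control and -0.417 under NORAD siRNA.

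NORAD siRNA in SAM68 knockout HCT116 left 27.7% of NORAD, 66.0 ± 16.1 CPM against 238 ± 19.1 (SD, n = 2). NORAD fell by 1.85 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00609), and it was again the called gene, 1 of 13764. Without knockout control siRNA replicate 2 it stood at -1.78 with an adjusted p of 0.0542, the highest of its 6 alternatives, whose lowest was 2.2e-27, and no gene was called by edgeR. PUM2 (0.19, adjusted p = 0.549) and the residual KHDRBS1 mRNA (0.17, 0.637) did not pass the edgeR test. Mitosis genes lay higher, 37 of 46 with a median log2 of 0.223 (camera adjusted p = 9.37e-09; adjusted p = 0.786 with an estimated correlation). The cohesion factor ESCO2 (0.51 ± 0.11), the spindle protein HMMR (0.50 ± 0.12) and the checkpoint protein MAD2L1 (0.46 ± 0.12) led them, and 6 members rose adjusted over the list alone, against 0 over all genes. Reported Pumilio targets lay higher in 16 of 18 members, with a median of 0.207 (camera adjusted p = 0.000294; adjusted p = 0.786 with an estimated correlation), among them the cyclin CCNE2 (0.63 ± 0.17), the chromatin protein DEK (0.35 ± 0.11) and the cap-binding protein EIF4E (0.31 ± 0.10), with none called over all genes or adjusted over the list alone. DNA replication and repair genes lay higher in 36 of 46, with a median of 0.121 (camera adjusted p = 0.00869; adjusted p = 0.786 with an estimated correlation), led by RAD51AP1 (0.47 ± 0.13), PRIM1 (0.31 ± 0.10) and RFC3 (0.32 ± 0.11).

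Lower in the same comparison lay integrated stress response genes, 17 of 21 with a median of -0.223 (camera adjusted p = 0.00116), NF-kB and inflammatory genes, 13 of 14 with a median of -0.237 (0.00657), and immediate early genes, 17 of 24 with a median of -0.133 (0.0258). Each had an adjusted p = 0.786 with an estimated correlation. Examples were PPP1R15A (-0.64 ± 0.20) and the amino acid transporters SLC7A5 (-0.36 ± 0.13) and SLC3A2 (-0.32 ± 0.11), the NF-kB subunits RELB (-0.50 ± 0.16) and NFKB2 (-0.26 ± 0.10) with TNFAIP2 (-0.25 ± 0.11), and the transcription factors NR4A1 (-0.51 ± 0.12), JUN (-0.46 ± 0.16) and FOSL1 (-0.37 ± 0.10). Over 6 alternatives PPP1R15A ranged from -0.94 to -0.27, SLC7A5 from -0.55 to -0.2 and JUN from -0.7 to -0.18. Adjusted over the list alone NR4A1 fell, and no member of these 3 lists or of the replication list otherwise passed, over all genes or adjusted over the list alone. The mitosis list (medians 0.143 to 0.256, the lowest without control siRNA replicate 1) and the reported Pumilio targets (0.143 to 0.255) were called in each fit without 1 library. Without control siRNA replicate 2 the calls of stress response (camera adjusted p = 0.0792, median -0.178), NF-kB (0.299, median -0.278) and immediate early genes (0.593, median -0.01) were lost. Without NORAD siRNA replicate 1 the stress response (0.0721, median -0.187) and immediate early (0.161, median -0.062) calls were lost, and without NORAD siRNA replicate 2 those of NF-kB (0.178, median -0.265) and replication genes (0.127, median 0.083). Medians otherwise reached -0.277 for immediate early and 0.056 for replication genes without control siRNA replicate 1, and -0.213 for immediate early and -0.365 for stress response genes without NORAD siRNA replicate 2.

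The unadjusted p was below 0.05 for 1558 genes in the knockout, 961 higher and 597 lower, against 688 expected by chance, and DESeq2 called 9. The excess over chance depended on single libraries: the count was 614 without control siRNA replicate 1, 559 without NORAD siRNA replicate 1 and 2476 without control siRNA replicate 2. It was 736 of 12167 genes with the GC and length offset. EdgeR called 4 genes without NORAD siRNA replicate 1. The groups did not overlap for 43.5% of genes, against 33.3% by chance. Log2 fold changes fell as GC content rose, in the 3′ UTR (rho -0.671) and in the rest of the transcript (-0.628). For 3′ UTR GC content, replicate 2 over replicate 1 gave rho -0.546 under control and 0.01 under NORAD siRNA. With the GC and length offset the median of reported Pumilio targets was 0.037 (camera adjusted p = 0.31) and that of mitosis genes 0.097 (4.81e-05). Replication (0.073, 0.0358), stress response (-0.138, 0.000562) and NF-kB genes (-0.113, 0.0199) kept their calls at smaller medians. These calls rest on the preset correlation, and the offset does not model the GC content of the rest of the transcript.

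The difference of the NORAD siRNA effect between knockout and wild-type HCT116 asks whether loss of SAM68 changes the response. NORAD itself differed by 0.45 ± 0.21 on the log2 scale (edgeR adjusted p = 0.642) and PUM2 by 0.28 ± 0.18, neither past the threshold. Mitosis genes responded more positively in the knockout, 35 of 46 with a median difference of 0.199 (camera adjusted p = 5.06e-05; adjusted p = 0.786 with an estimated correlation), with SPC25 (0.66 ± 0.21), ESCO2 (0.65 ± 0.16) and HMMR (0.58 ± 0.17) leading. Reported Pumilio targets did so in 16 of 18, with a median of 0.212 (camera adjusted p = 0.000612; adjusted p = 0.786 with an estimated correlation), led by CCNE2 (0.68 ± 0.25), DEK (0.55 ± 0.16) and EIF4E (0.38 ± 0.14). Neither list had a member called by edgeR over all genes or adjusted over the list alone. Both were called in each fit without 1 library, with medians of 0.124 (without wild-type control siRNA replicate 2) to 0.252 for mitosis and 0.171 to 0.279 for Pumilio targets.

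EdgeR called 0 of 13764 genes for this difference, with 1048 at an unadjusted p below 0.05 against 688 expected by chance, and DESeq2 called 2. Single libraries moved that count to either side of chance. Without wild-type libraries it was 2026 (control siRNA replicate 1), 484 (control siRNA replicate 2) and 283 (NORAD siRNA replicate 1), and without knockout libraries 407 (control siRNA replicate 1), 2136 (control siRNA replicate 2) and 522 (NORAD siRNA replicate 1). With the GC and length offset it was 411 of 12167 genes. EdgeR called 1 gene without wild-type NORAD siRNA replicate 1, knockout control siRNA replicate 1, knockout control siRNA replicate 2 or knockout NORAD siRNA replicate 1. The difference fell as GC content rose, in the 3′ UTR (rho -0.692) and in the rest of the transcript (-0.649). With the same offset, the median was 0.031 for reported Pumilio targets (camera adjusted p = 0.674) and 0.078 for mitosis genes (0.0357).

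SAM68 knockout against wild-type HCT116 under control siRNA gave the most calls of the 6 comparisons, 43 of 13764 genes, 23 higher and 20 lower. KHDRBS1 fell by 2.71 ± 0.15 on the log2 scale (edgeR adjusted p = 0.000155), with 15.3% of the wild-type mRNA remaining. NORAD (-0.01 ± 0.15, adjusted p = 0.986) and PUM2 (0.07) did not pass. SCUBE1, a secreted and membrane glycoprotein, rose by 2.88 ± 0.20 (adjusted p = 0.000447), the kallikrein proteases KLK5 by 2.23 ± 0.24 (0.00442) and KLK7 by 1.17 ± 0.13 (0.00485), and the laminin chain LAMA3 by 1.74 ± 0.18 (0.00335). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose to 335 ± 6.59 from 148 ± 18.4 CPM (SD, n = 2), by 1.18 ± 0.12 on the log2 scale (0.0031). The other large increases were NRP1 (1.32 ± 0.19), TP53I3 (1.26 ± 0.19), TP53INP1 (1.21 ± 0.14), the glutamate transporter SLC1A3 (1.13 ± 0.14) and the peroxisomal lyase HACL1 (1.08 ± 0.12). KHDRBS3, a relative of SAM68 that was singled out after its values were seen, rose to 18.28 ± 3.73 from 9.15 ± 0.43 CPM (edgeR adjusted p = 0.0476).

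Among decreases in the knockout, ENKD1 fell by 3.18 ± 0.25 on the log2 scale to 0.81 ± 0.106 from 7.32 ± 1.17 CPM (SD, n = 2; edgeR adjusted p = 0.000739). BTBD1 fell by 1.96 ± 0.12 (adjusted p = 0.000155), the fatty acid ligase ACSL5 by 1.52 ± 0.14 (0.00252), the nuclear receptor NR2F1 by 1.42 ± 0.14 (0.0031), the olfactory receptor OR51B4 by 1.40 ± 0.18 (0.0122) and the protein kinase A subunit PRKACB by 1.11 ± 0.15 (0.0186). XXYLT1 fell by 1.35 ± 0.14 (0.00335) and TMEM44 by 1.19 ± 0.17 (0.0186). Both lie on chromosome 3 with the called genes CCDC50, OPA1 and LSG1, in a run of 16 neighbouring tested genes that were all lower in the knockout under both siRNAs. The ends of that run were set, and the last 3 genes named, after the values were seen. TMEM44 has an antisense neighbour, TMEM44-AS1, and is uncertain for that reason. A row of EIF3CL at 0 against 5.12 ± 1.25 CPM is a genomic copy, and its 3 rows summed to 839.48 and 770.78 against 828.42 and 811.63 CPM.

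**Figure D2:**
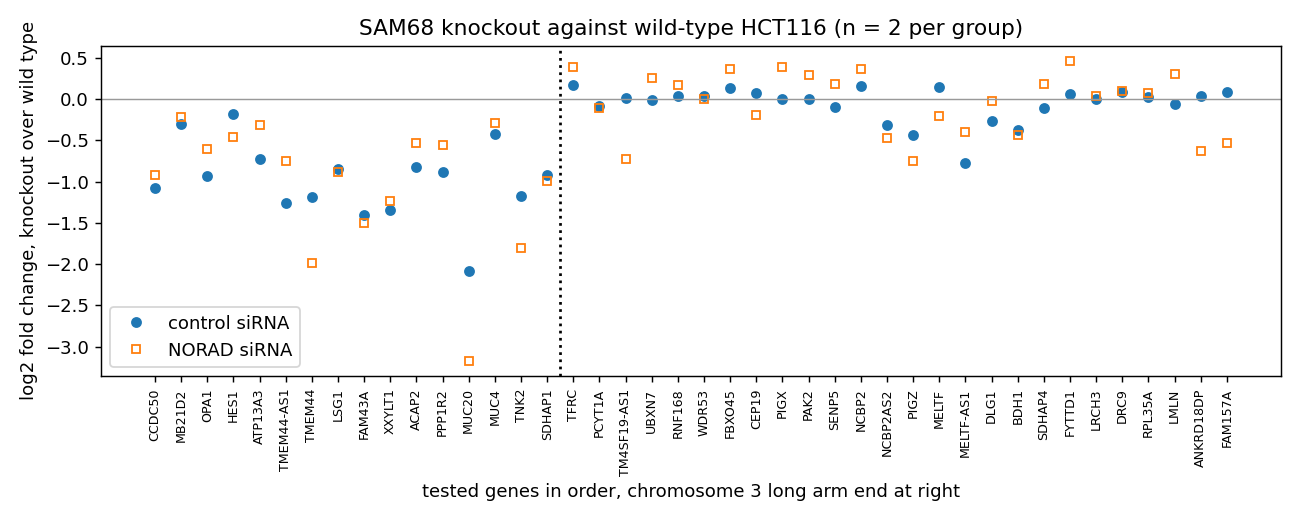
Log2 fold change of knockout over wild-type HCT116 for the 42 tested genes from CCDC50 to the end of chromosome 3, in gene order (assembly GRCh38.p14), under control siRNA (filled circles) and NORAD siRNA (open squares), n = 2 per group. The 16 genes left of the dotted line, which was placed after the values were seen, are all below 0, with medians of -0.925 and -0.816.

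Without knockout control siRNA replicate 2 the knockout comparison gave 20 calls, and without wild-type control siRNA replicate 1 it gave 27. The first of these ended the calls of OR51B4 (-1.15, edgeR adjusted p = 0.0835), SLC1A3 (1.03, 0.0648), TP53INP1 (1.09, 0.0539), SESN1 (0.99, 0.0539) and the EIF3CL row (0.0715). PRKACB lost its call without knockout control siRNA replicate 1 (-1.10, 0.0952) or 2 (-1.13, 0.129) or wild-type control siRNA replicate 1 (-1, 0.0732). NRP1 lost it without wild-type control siRNA replicate 1 (1.45, 0.069) or 2 (1.21, 0.109) or knockout control siRNA replicate 2 (1.16, 0.161), and TP53I3 without wild-type control siRNA replicate 2 (1.09, 0.119) or knockout control siRNA replicate 1 (1.12, 0.145) or 2 (1.38, 0.0893). TMEM44 lost its call without any 1 of the 4 libraries, at -1.19 (0.0832) and -1.20 (0.0629) without wild-type control siRNA replicates 1 and 2 and at -1.09 (0.0874) and -1.35 (0.0648) without the knockout ones. Over 6 alternatives the highest adjusted p of each of these genes is among those given, and the lowest was 1.48e-06 for OR51B4, 6.59e-09 for SLC1A3, 4.14e-07 for TP53INP1, 2.53e-05 for SESN1, 1.84e-06 for the EIF3CL row, 5.13e-09 for PRKACB, 0.000276 for NRP1, 1.01e-05 for TP53I3 and 0.000541 for TMEM44. DESeq2 called 114 genes, and 7 were called by edgeR from the 4 compared libraries alone, 1 higher and 6 lower. That fit is not among the 6 alternatives, so at most 1 of the named increases passed in it. EdgeR called 254 with the replicate number as a block, 145 with the GC and length offset and 272 without a filter. The unadjusted p was below 0.05 for 1269 genes, against 688 expected by chance, with 837 without knockout control siRNA replicate 2 and 1795 without knockout control siRNA replicate 1. The groups did not overlap for 34.6% of genes, against 33.3% by chance.

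Target genes of the tumour suppressor p53 lay higher in the knockout, in 25 of 27 members, with a median log2 fold change of 0.489 (camera adjusted p = 1.07e-30; adjusted p = 0.0518 with an estimated correlation; fry adjusted p = 0.0112). EdgeR called 6 of them over all genes, CDKN1A, TP53I3, TP53INP1, SESN1 (log2 1 ± 0.12), BTG2 and ZMAT3 (the last 2 named after their values were seen), and 17 rose adjusted over the list alone. The list was called in each fit without 1 library, with medians of 0.424 to 0.638. With the GC and length offset the median was 0.481. Relative to the mean of the 8 HCT116 libraries, the list median was -0.284 ± 0.050 in wild type and 0.241 ± 0.089 in knockout under control siRNA (SD, n = 2). The exact permutation p of this difference was 0.333, the smallest that 2 against 2 libraries allow.

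**Figure D3:**
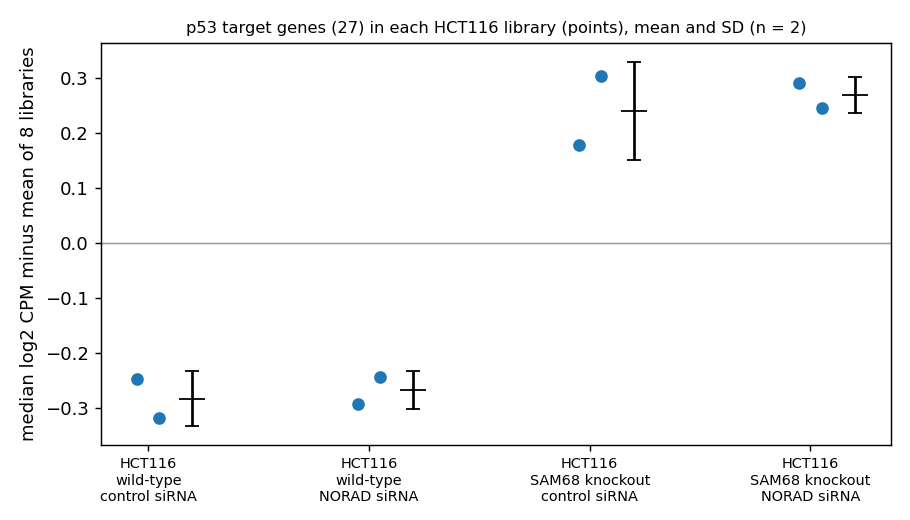
Median log2 CPM of the 27 tested p53 target genes minus the mean of the 8 HCT116 libraries, for each library (points), with mean and SD of each group (n = 2). Both knockout groups lie above 0, with means of 0.241 and 0.269, and both wild-type groups below, with -0.284 and -0.268.

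NF-kB and inflammatory genes lay higher in the knockout, 10 of 14 with a median of 0.203 (camera adjusted p = 0.0375; adjusted p = 0.786 with an estimated correlation), among them the chemokine CXCL8 (1.80 ± 0.54), TNFAIP3 (0.61 ± 0.17) and LIF (0.40 ± 0.10), and these 3 rose adjusted over the list alone. CXCL8 varied widely, at 19.9 ± 15.1 against 5.86 ± 2.17 CPM (SD, n = 2), with a log2 fold change of 0.69 to 2.38 over 6 alternatives. Endoplasmic reticulum chaperones lay higher in 15 of 16, with a median of 0.161 (camera adjusted p = 0.0281; adjusted p = 0.786 with an estimated correlation) and DNAJB9 (0.57 ± 0.27), CRELD2 (0.28 ± 0.14) and DNAJB11 (0.22 ± 0.10) as examples. DNA replication and repair genes lay lower in 38 of 46, with a median of -0.104 (camera adjusted p = 0.0017; adjusted p = 0.786 with an estimated correlation) and MCM7 (-0.27 ± 0.10), POLE (-0.26 ± 0.10) and MCM3 (-0.24 ± 0.09) as examples. None of these 3 lists had a member called by edgeR over all genes, and the chaperones and replication genes had 0 adjusted over the list alone. The NF-kB call was lost without wild-type control siRNA replicate 1 (camera adjusted p = 0.174, median 0.242) or 2 (0.155, 0.247) or knockout control siRNA replicate 2 (0.263, 0.189). The chaperone call was lost without wild-type control siRNA replicate 1 (0.248, median 0.097) or knockout control siRNA replicate 2 (0.59, median 0.093), and the replication call without wild-type control siRNA replicate 2 (0.216, median -0.059) or knockout control siRNA replicate 1 (0.0513, median -0.078). Log2 fold changes of this comparison fell as GC content rose, in the 3′ UTR (rho -0.323) and in the rest of the transcript (also -0.323). For 3′ UTR GC content, replicate 2 over replicate 1 gave rho -0.478 in wild-type and -0.546 in knockout cells.

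Genes with at least 2 Pumilio motifs in their 3′ UTR, the class that the series title concerns, were compared with genes without the motif. The differences of medians are between these classes. The camera tests without matching set the motif genes against all other tested genes, including those with a single copy. After NORAD siRNA in wild-type HCT116 their median log2 fold change lay lower than that of the others, with a difference of -0.086 (1268 against 8596 genes, camera adjusted p = 1.99e-06; adjusted p = 0.525 with an estimated correlation). In knockout HCT116 it lay higher by 0.155 (camera adjusted p = 5.81e-07), and the effects differed by 0.243 between the genotypes (5.46e-10), each with an adjusted p = 0.525 with an estimated correlation. The difference was -0.111 for SAM68 siRNA and -0.105 for SAM68 plasmid in U2OS, over 1447 against 9377 genes (camera adjusted p = 9.22e-05 and 1.17e-05; adjusted p = 0.525 with an estimated correlation for each). It was 0.073 for knockout against wild type (camera adjusted p = 0.0189; adjusted p = 0.649 with an estimated correlation). In the last comparison edgeR called 5 members higher (TP53INP1, F3, ZMAT3, AREG and ITGA2) and 2 lower (OPA1 and CCDC50) over all genes, and 8 higher and 3 lower adjusted over the list alone, and in the other 5 comparisons 0 by either adjustment.

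Motif genes differ from the others in their 3′ UTRs, with a median length of 3678.5 bases against 1004 and a GC content of 36.7% against 46.2% in HCT116. Against genes matched on 3′ UTR length and expression, the difference was -0.047 in wild-type (camera adjusted p = 0.00362) and 0.113 in knockout cells (1.61e-05), 0.167 between them (2.66e-06), 0.041 for knockout against wild type (0.267), and -0.10 and -0.028 for SAM68 siRNA and plasmid (0.000381 and 0.11). Matched also on GC content, a match chosen after seeing the data, the differences were -0.013, -0.031, -0.014, -0.013, -0.022 and -0.014 in the same order, with camera adjusted p from 0.676 to 0.717. This match was less close on length. In HCT116 the matched genes had a median of 2948.5 bases, against 3613 in the match without GC content. In U2OS the median was 2952 against 3779 in the motif genes. The scrambled motif gave -0.081 in wild-type and 0.211 in knockout cells and 0.306 between them. Its genes were not required to lack the Pumilio motif, and the overlap was not counted. These values therefore cannot by themselves tell a trend with 3′ UTR length or GC content from a Pumilio effect.

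**Figure D4:**
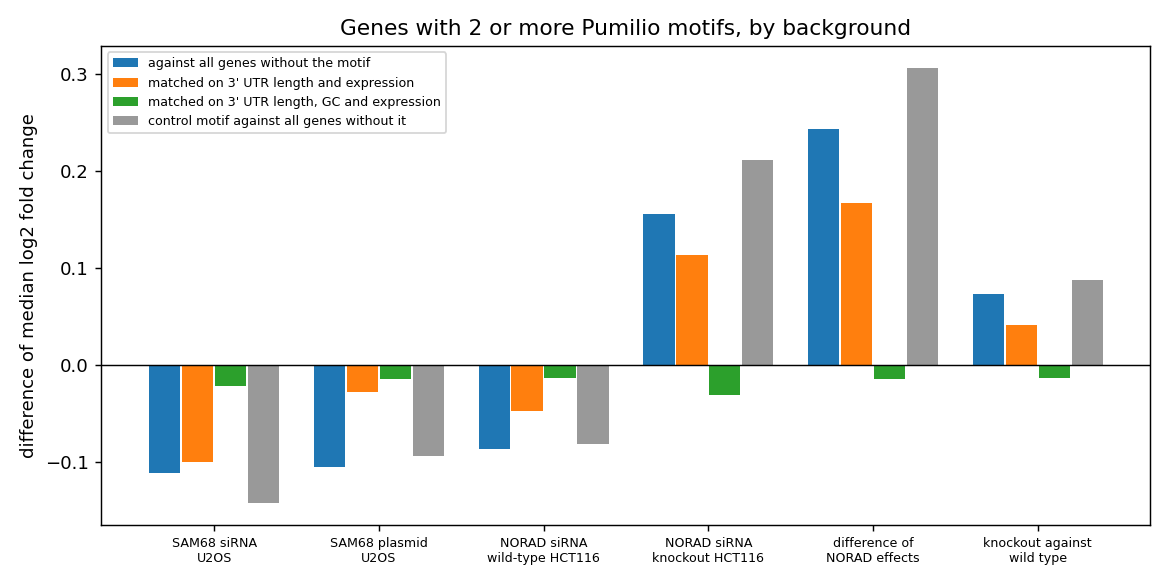
Difference in median log2 fold change between genes with at least 2 Pumilio motifs and genes without, for the 6 comparisons (bars from 0), against all genes without the motif, against genes matched on 3′ UTR length and expression, and against genes matched also on 3′ UTR GC content; grey bars give a scrambled control motif. In knockout cells after NORAD siRNA the bars stand at 0.155, 0.113, -0.031 and 0.211.

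Single libraries moved or reversed the unmatched motif differences. In wild-type HCT116 the difference was -0.177 and 0.008 without control siRNA replicates 1 and 2, and -0.024 and -0.144 without NORAD siRNA replicates 1 and 2. In knockout HCT116 it was 0.024 without control siRNA replicate 1 and 0.304 without control siRNA replicate 2. The difference between the genotypes was 0.142 without wild-type control siRNA replicate 2, 0.113 without knockout control siRNA replicate 1 and 0.402 without knockout control siRNA replicate 2. For knockout against wild type it was -0.034 and 0.163 without wild-type control siRNA replicates 1 and 2, and 0.20 and -0.062 without the knockout ones. In U2OS the SAM68 siRNA difference was 0.111 without SAM68 siRNA replicate 2, -0.409 without its replicate 1 and -0.072 without control siRNA replicate 1. The SAM68 plasmid difference was 0.075 and -0.314 without SAM68 plasmid replicates 1 and 2, and -0.022 and -0.19 without control plasmid replicates 1 and 2.

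Fold changes of different comparisons were set against each other across genes, which are not independent replicates. SAM68 siRNA and SAM68 plasmid in U2OS correlated at r = 0.016 over 15658 genes, with the same sign for 50.8%, and at -0.048 without SAM68 plasmid replicate 1 to 0.061 without SAM68 plasmid replicate 2. NORAD siRNA in wild-type and in knockout HCT116 correlated at -0.074 over 13764 genes, with the same sign for 40% and NORAD called lower in both. Without wild-type control siRNA replicate 2 this r was 0.006, without knockout control siRNA replicate 1 it was 0.014, and without wild-type control siRNA replicate 1 it was -0.135. SAM68 siRNA in U2OS correlated at 0.038 with SAM68 knockout in HCT116 and at 0.024 with NORAD siRNA in wild-type HCT116, over 13004 genes. Without single libraries the first of these ranged from -0.077 (U2OS control siRNA replicate 2) to 0.141 (SAM68 siRNA replicate 2), and the second from -0.088 (wild-type control siRNA replicate 2) to 0.129 (SAM68 siRNA replicate 1). Over genes above 10 CPM the 4 correlations were -0.015, -0.29, -0.111 and 0.269 in the order given. The fold changes carry trends with 3′ UTR GC content. Their rho was 0.394 for SAM68 siRNA, 0.233 for the plasmid and 0.377 for NORAD siRNA in wild type. It was -0.671 for NORAD siRNA in knockout and -0.323 for knockout against wild type. No correlation was corrected for GC content, so shared or opposed responses cannot be told from these trends.

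NORAD siRNA in wild-type cells and SAM68 knockout share their control libraries, and their r was 0.303, where unchanged groups against those controls gave 0.504 in 30 simulations. The observed r was 0.62 and 0.539 without wild-type control siRNA replicates 1 and 2, 0.171 without knockout control siRNA replicate 1 and -0.116 over genes above 10 CPM, for which no unchanged groups were simulated, so its side of the chance value is not settled. The covariance was 0.048 against 0.0439 simulated, and the same sign held for 47.1% of genes against 66.7%. No gene was called in both. The simulated values already hold the effect of the shared controls, which cannot be split with 2 libraries. With all libraries, r and the same sign lay below the simulated values and the covariance above. The draws were independent for each gene, without the GC trends of the 2 comparisons (rho 0.377 and -0.323 with 3′ UTR GC content). The simulated values are therefore an uncertain measure of chance.

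Of the 18 gene lists, 17 had enough tested members, and 19 of their 102 tests were called by camera with the preset correlation, 0 with an estimated correlation and 1 by fry. Without single libraries, 6 of the 19 calls held in each fit, 13 were lost in at least 1 and 2 of these reversed in direction. The lists with no call in any comparison, without an offset, were cholesterol synthesis and uptake (medians -0.096 to 0.039, camera adjusted p from 0.628), colon epithelial markers (-0.223 to 0.093, from 0.0651), mesenchymal and bone markers (-0.127 to 0.087, from 0.264), interferon-stimulated genes (-0.18 to 0.198, from 0.0651), histone genes (-0.193 to 0.242, from 0.128), reported SAM68 targets (-0.083 to 0.21, from 0.0958) and STAR family and NORAD protein partners (-0.019 to 0.066, from 0.442). With the GC and length offset, interferon-stimulated genes were called lower after SAM68 siRNA (median -0.155, camera adjusted p = 0.031), and STAR family and NORAD protein partners were called lower after NORAD siRNA in the knockout (-0.096, 0.0454) and in the difference between the genotypes (-0.102, 0.0399). EdgeR called 1 member of these 7 over all genes, KHDRBS3 in the knockout, which also rose adjusted over the list alone, as did the histone gene H2BC5 and the reported SAM68 target ALDH1A3 there. Of the blood, endothelial and liver markers, 3 genes passed the filter in U2OS (PTPRC, CD68 and VWF) and 1 in HCT116 (CD68), too few for a test. In the knockout comparison, ITGA2, named after its values were seen, was the called member of the reported Pumilio targets (0.68 ± 0.11, edgeR adjusted p = 0.0476), and it also rose adjusted over the list alone, as did the immediate early genes DUSP4 and PHLDA1. Members named for passing a list's own adjustment or the motif list's test were singled out after their values were seen.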

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

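The match on 3′ UTR GC content, the GC and length offset and the list tests without single libraries were chosen only after the results were seen. A test of the difference itself called a different response to NORAD siRNA in knockout and wild-type HCT116 for 3 gene groups. These calls came only from camera with the preset correlation, and edgeR called 0 of 13764 genes. Mitosis genes had a median difference of 0.199 (camera adjusted p = 5.06e-05; adjusted p = 0.786 with an estimated correlation). Reported Pumilio targets had 0.212 (0.000612; adjusted p = 0.786 with an estimated correlation). Genes with at least 2 Pumilio motifs had 0.186, which lay 0.243 above genes without the motif. Camera, which set them against all other tested genes, gave an adjusted p of 5.46e-10 (0.525 with an estimated correlation). Fry gave the motif genes an unadjusted p of 0.196. Against genes matched on 3′ UTR length, expression and GC content, whose median was 0.20, the difference of the motif genes was -0.014 (-0.033 to 0.023 without single libraries) and its call was lost (camera adjusted p = 0.717). The match on length was not close, with a median of 2948.5 bases against 3678.5 in the motif genes. With the GC and length offset the call for reported Pumilio targets was lost, because their median fell from 0.212 (quartiles 0.168 to 0.325) to 0.031 (-0.049 to 0.146; camera adjusted p = 0.674). The median of mitosis genes fell from 0.199 (0.002 to 0.397) to 0.078 (-0.02 to 0.196; 0.0357).

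The motif genes lay lower after NORAD siRNA in wild-type and higher in knockout cells. Because Pumilio proteins repress their targets, weaker repression in the knockout would raise the motif genes. Heptamers inside the motif argue against weaker repression there that would rank their median in the highest 5% of all heptamers. After correction for 3′ UTR GC content, 3′ UTR length and expression that median stood at percentile 36 (32.4 to 60.9 without single libraries), with single motif heptamers from 32.9 to 95.6. In wild type, where stronger repression would lower the motif genes, the median stood at percentile 24.7 (26.1 to 50.7 without single libraries). Stronger Pumilio repression there cannot be told apart from its absence. The 40 permutations used the values of another comparison, knockout against wild type under control siRNA. They spanned 15.6 to 74.6, a range that holds both 24.7 and 36, so a smaller change of repression in the knockout, in either direction, stays open. Against genes matched on 3′ UTR length, GC content and expression the differences were -0.013 and -0.031, and replicates differed among themselves by a GC trend of rho -0.478 under control and -0.417 under NORAD siRNA in wild type, and of -0.546 under control but 0.01 under NORAD siRNA in knockout, where both NORAD siRNA libraries had a like trend (-0.589 and -0.662 against the mean of the cell line). Leaving out 1 control library brought the unmatched differences to 0.008 in wild type (replicate 2) and 0.024 in knockout (replicate 1). GC trends that vary from library to library are therefore a candidate explanation of the wild-type shift and, through the control libraries, of the knockout shift, while a GC-linked trend that belongs to NORAD siRNA in the knockout, and a smaller response of Pumilio targets that such trends hide, stay open.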

How the results depend on the processing

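The offset for 3′ UTR GC content and length, leaving out copy rows, the GC match and the lists without single libraries were chosen only after the results were seen. Other size factors, the filter of 1 CPM, the length offset and the fold of 1.2 kept each count of called genes within 1.5 times. Named genes kept direction and side of the threshold in 611 of their values, lost it in 25 and gained it in 4. List tests did so in 513, with 62 weaker, 15 stronger, 2 reversed and 2 called only under the alternative with the opposite sign. These last were STAR family and NORAD protein partners with the GC and length offset, at -0.096 for NORAD siRNA in knockout (0.058 without it) and -0.102 for the difference of effects (0.066).

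In the order SAM68 siRNA, SAM68 plasmid, NORAD siRNA in wild type, NORAD siRNA in knockout, difference of effects, and knockout against wild type, DESeq2 called 7, 4, 5, 9, 2 and 114 genes, and edgeR without a filter 27, 15, 33, 61, 30 and 272. With only the compared libraries, which leaves fewer degrees of freedom, edgeR called 0 for SAM68 siRNA, 2 for the plasmid, 2 and 7 for NORAD siRNA, and 7 for the knockout. Without copy rows it called 0 for SAM68 siRNA and 0 for the plasmid, whose called gene is such a row. With the GC and length offset it called 1 for SAM68 siRNA, another gene than without it and lower instead of higher, 0 for the plasmid, 0 and 0 for NORAD siRNA, and 145 for the knockout. NORAD and the ZBED1 copy row have no annotated 3′ UTR and drop out of these fits by construction. Without single libraries the counts were 0 to 5, 0 to 4, 1 to 2, 0 to 4, 0 to 1 and 20 to 41, and 15 to 26 named genes were called (25 with all libraries).

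With the replicate number as a block, edgeR called 0, 0, 3, 7, 2 and 254 genes, and nested in genotype 13, 13 and 5 for the NORAD comparisons and their difference. Genes at an unadjusted edgeR p below 0.05 then numbered 194, 97, 611, 3190, 2603 and 2290. Without the block they numbered 166, 86, 181, 1558, 1048 and 1269. The labels give replicates no shared day, and deviations of same-numbered libraries correlated at 0.079 to 0.317 in HCT116 and -0.207 to 0.393 in U2OS, so this is a hint from the data, not the design.

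With an estimated correlation the Pumilio motif differences, -0.111, -0.105, -0.086, 0.155, 0.243 and 0.073, no longer passed. Matched on length and expression the plasmid (-0.028) and knockout (0.041) differences no longer passed, and matched also on GC content none did (-0.022, -0.014, -0.013, -0.031, -0.014 and -0.013), with the last 3 turned in sign. Without single libraries they ranged from -0.409 to 0.111, -0.314 to 0.075, -0.177 to 0.008, 0.024 to 0.304, 0.113 to 0.402 and -0.062 to 0.20; those of the plasmid, wild type and knockout comparison that fell short or turned included -0.022, -0.024 and -0.034. Of the 19 list calls, 0 held with an estimated correlation and fry made 1. Without single libraries the immediate early median after SAM68 siRNA ranged from -0.104 to 0.608 and the ribosomal one after the plasmid from -0.134 to 0.539.

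Correlations across genes ranged, without single libraries, from -0.048 to 0.061 for SAM68 siRNA with plasmid, -0.135 to 0.014 for NORAD siRNA in both genotypes, -0.077 to 0.141 for SAM68 siRNA with knockout, 0.171 to 0.62 (0.539 without wild-type control siRNA replicate 2) for NORAD siRNA with knockout, and -0.088 to 0.129 for NORAD siRNA with SAM68 siRNA. Over genes above 10 CPM the last 4 were -0.29, -0.111, -0.116 and 0.269. Where no reason is given the cause was not tested.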

Other observations

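Knockout against wild type under NORAD siRNA, and the shorter segment and the comparison of p53 targets between cell lines below, were tests chosen only after the results were seen. Under NORAD siRNA, edgeR called 1590 genes higher and 905 lower in SAM68 knockout than in wild-type HCT116. All 43 genes called under control siRNA had the same sign there, and 42 were called in the same direction. CDKN1A rose again, by 1.02 on the log2 scale (edgeR adjusted p = 0.00518), and KHDRBS1 stood at -2.44. These log2 fold changes fell as 3′ UTR GC content rose (Spearman rho -0.695 across genes, which are not independent replicates).

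The p53 targets lay higher in the knockout in each fit without 1 library, with a lowest median of 0.424, which argues against 1 deviating library. Under NORAD siRNA, in other libraries, 23 of 27 members were higher with a median of 0.56 and 15 called, which argues against the control siRNA libraries as the cause. After SAM68 siRNA in U2OS the median was -0.024 (quartiles -0.122 to 0.048), and -0.028 to 0.174 without single libraries (the highest without SAM68 siRNA replicate 1), which argues against an effect of SAM68 loss in both cell lines that would put U2OS at 0.244 or above, a bound set after the values were seen, where the knockout stood at 0.489. Both SAM68 siRNA libraries lay below both controls, at -0.016 ± 0.071 against 0.088 ± 0.023 (SD, n = 2; exact permutation p = 0.333, the smallest possible). A smaller like effect, or one that needs a fuller loss than the 26.2% of KHDRBS1 mRNA left in U2OS, stays open, as does a difference between the knockout cells and their wild-type parent that does not come from SAM68, since the number of knockout clones is not given in the sources used here.

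Of the 42 tested genes from CCDC50 to the end of chromosome 3, 5 were called lower in the knockout. Loss of the whole stretch predicted a median of -0.5 or lower for the other genes, and they stood at -0.083 under control and -0.206 under NORAD siRNA, which argues against it. The 16 genes from CCDC50 to SDHAP1 differed between genotypes by -0.907, with medians of -0.468 ± 0.050 in the knockout and 0.439 ± 0.028 in the wild-type libraries (SD, n = 4), while the 25 genes before and 26 after differed by -0.01 and 0.038. Because the ends of this segment were set from the same values, loss of 1 of its copies in the knockout cells is a hypothesis that may account for the decreases of XXYLT1, TMEM44, CCDC50, OPA1 and LSG1.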
